A study of Mus musculus with 12 samples.

How the data were processed

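The series holds 12 libraries from mouse striatum: 3 CLIP and 3 input libraries from mice given cocaine, and 3 CLIP and 3 input libraries from mice given saline. Per the labels' protocols, frozen tissue was lysed in RIPA buffer and crosslinked with ultraviolet light, RNA was precipitated with a monoclonal antibody against YTHDF1, RNA ends were repaired with T4 polynucleotide kinase, and libraries were made with a small RNA adapter-ligation kit. That kit keeps the strand of the RNA. The labels name striatal neurons as the cell type, but the protocol describes lysis of whole tissue. The submitters' processing notes name cutadapt, STAR and mm10, without versions or settings. The names of the deposited tables point to CLIPper as the peak caller. Its version and threshold, the handling of duplicate reads, the use of the input libraries and the rule that gave a peak to a gene are not given in the sources used here.

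The deposited values are whole-number counts of CLIP peaks per gene, not of reads, in 2 tables of 3 library columns each, per the file headers and values. Each table also holds the authors' mean of the 3 columns, a deposited value that was used only to check the columns. A table was assigned to a treatment by a single letter, c or s, within its name, which is the letter that opens the library names in the labels. Its columns carry no replicate number, so each is a replicate of its treatment with no number of its own. Tested on the files, every listed gene had at least 1 peak in each of the 3 libraries, and a mean above 6 peaks in the cocaine table and above 1 in the saline table. Genes below these cutoffs are not in the tables, and a missing gene was never set to 0. The tables hold no peak positions, strands, strengths or sequences and no input values. The planned comparisons of peak overlap, location in transcripts, distance to the stop codon, the m6A consensus motif, peak strength and CLIP against input could therefore not be made.

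There were 1084 lines for 1049 genes in the cocaine table and 463 lines for 449 genes in the saline table, because a few genes were repeated under several symbols; each gene was counted once. Of the 1247 genes in either table, 348 have no symbol and 5 have several, and 891 of the 894 with 1 symbol (99.7%) were found by symbol in the RefSeq annotation of GRCm38.p6, the assembly that mm10 names. Coordinates, gene classes and overlaps come from that annotation, which gives no strand here. Genes without a symbol could not be classed as coding or non-coding.

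Depth is known only as peaks. The cocaine libraries totalled 25070.0 ± 402.9 peaks (SD, n = 3) and the saline libraries 3817.7 ± 114.7. Spearman correlations between libraries of a table, across genes, were 0.569 to 0.596 in cocaine and 0.633 to 0.689 in saline, and the median coefficient of variation of a gene was 37.3% and 36.5%. No 2 columns were copies: 4.1 to 6.48% of genes had equal values in a pair of cocaine columns and 20.9 to 21.8% in a pair of saline columns. The labels do not say that libraries came from separate animals, so p-values measure only the spread between these samples, which may be technical. Peaks of 1 gene are not independent, and intervals cover counting error only.

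Overlap of the gene lists was set against the product of the list lengths over the number of coding genes. Gene lists were tested with 2-sided Fisher's exact tests, genes of 1 table alone against the rest of the named genes, with Benjamini-Hochberg adjustment. Totals were compared by an exact permutation test, and ratios of coding and non-coding genes by a permutation test with 100000 resamples. Because the columns are counts per library, the 251 genes in both tables were tested with edgeR 4.0.16 (TMM factors, filterByExpr, quasi-likelihood test, R 4.3.3), cocaine against saline CLIP libraries, with an FDR of 0.05. The plan had been to contrast CLIP with input, which these tables do not allow. A library's total covers only the tested genes among those in both tables, so the test compares shares of those peaks. The log2 differences in share given below are edgeR's values on totals scaled by TMM factors, unless said otherwise. They are not plain ratios of shares. The common dispersion gave a biological coefficient of variation of 22.1%. Tested on simulated data (10 simulations, 1247 genes, 200 changed, the cutoffs of both tables applied), the same test of cocaine against saline recovered 26.5% of 2-fold and 83.7% of 4-fold changes, called 0.42% of unchanged genes and made 0 calls when no gene changed. The simulated tables shared more genes than the real ones, so a mean of 456.1 genes were tested there against 202 here, and these rates may differ in the real data. DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and SciPy 1.17.1 were also used.

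Groups, tests, gene lists and the first set of alternatives were fixed before the data were examined. The naming rule then written ranked genes by the caller's p; the tables hold none, nor a score or width, so the mean number of peaks took its place. It names 10 genes in both tables (ranked by the worse of their 2 ranks), 10 in cocaine alone, 10 in saline alone, the 5 with most peaks in each table, and the listed members of each fixed list. The following were added after the tables were seen: the 10 named genes with the smallest p in each direction of the edgeR test, the comparisons of coding with non-coding genes, the common cutoff of a mean above 6 peaks, the test on raw peaks and on genes above doubled cutoffs. The 2 genes named by identifier, the overlaps with neighbouring genes and the distance from Ankk1 to Drd2 were also picked out after their values were seen. Alternatives tried were a stricter cutoff, lists of equal length, a smaller background, DESeq2, no filter, leaving out each library, no TMM factors, leaving out the gene with most peaks, and those named above.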

Results

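YTHDF1 is a cytoplasmic protein that binds N6-methyladenosine (m6A) in RNA and is known to promote translation of the RNAs it binds. Its RNA targets were mapped in the striatum, the brain region that receives dense dopamine input, of wild-type C57BL/6J mice given cocaine or saline. The assay was CLIP-seq, in which protein and RNA are crosslinked by ultraviolet light and the RNA held by the protein is precipitated with an antibody and sequenced. The series holds 12 samples in 4 groups of 3: precipitated RNA (CLIP) and total input RNA from each treatment. The values analysed here are the number of CLIP peaks per gene in each of the 3 CLIP libraries of a treatment, in 1 table for cocaine and 1 for saline. Values of the 6 input libraries were not analysed here, so no level below is corrected for how abundant an RNA was. The cocaine libraries held 25528, 24770 and 24912 peaks in the genes listed for cocaine, and the saline libraries held 3789, 3720 and 3944 peaks in the genes listed for saline. The sequencing depth behind these peaks is unknown. The libraries have no replicate number in the tables and are called 1 to 3 by the order of their columns.

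The first comparison asks which RNAs carried YTHDF1 peaks in each treatment. Fgfr2, a fibroblast growth factor receptor, led the named genes in both tables, with 457.7 ± 33.6 peaks in cocaine and 102.7 ± 5.77 in saline (SD, n = 3 libraries each). It lies on chromosome 7 from 130162451 to 130266808 (mm10). Ctnna3, an alpha-catenin gene on chromosome 10 from 63430098 to 65003667, had 380.7 ± 9.87 peaks in cocaine and 36.0 ± 3.61 in saline. Syn3, which encodes a synapsin of synaptic vesicles, had 144.3 ± 12.2 and 39.3 ± 12 peaks. Wdr17 had 167.0 ± 22.5 and 48.7 ± 6.51 peaks. Most of the leading genes overlap a neighbour in the RefSeq annotation, Ctnna3 among others Lrrtm3, and Syn3 among others Timp3. Tsix, the antisense RNA of Xist, had 220.7 ± 4.51 peaks in cocaine and 47.7 ± 19.6 in saline. Ube3a, a ubiquitin ligase gene that overlaps the non-coding Snhg14, had 224.0 ± 19.9 and 26.7 ± 4.04 peaks. Kcnq1, a potassium channel gene that overlaps the non-coding Kcnq1ot1, had 222.3 ± 30.7 and 34.0 ± 8.0 peaks. Xist, Snhg14 and Kcnq1ot1 were in neither table under these symbols, but 348 of the 1247 listed genes have no symbol. Pigk, the non-coding Sorbs2os and the non-coding 9630028H03Rik completed the 10 leading shared genes that have a symbol, with 286.0 ± 53.5, 216.3 ± 16.4 and 215.7 ± 14.6 peaks in cocaine and 32.3 ± 6.66, 32.3 ± 8.50 and 34.3 ± 8.02 in saline. The tables give neither the strand nor the position of a peak, so peaks of a gene and of a gene that overlaps it cannot be separated. The gene with most peaks in both tables has no symbol in them (ENSMUSG00000092329) and had 1645 ± 125 peaks in cocaine and 825.3 ± 77.9 in saline.

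In all, 1049 genes were listed for cocaine and 449 for saline, and 251 were in both, which is 55.9% of the saline genes and 23.9% of the cocaine genes. Among protein-coding genes, 127 were shared, where 7.55 would be shared by independent lists drawn from all 21896 coding genes. That expected number is a lower bound, because the genes expressed in striatum were not known. The listed cocaine genes all had a mean above 6 peaks and the listed saline genes a mean above 1, so the lengths of the 2 lists cannot be compared directly. At a mean above 6 peaks in both, 137 saline genes remained against 1049 cocaine genes, and 132 of the 137 were in the cocaine table. The 5 that were not were Vac14, Npas1, Hhat, Dcaf10 and 1 gene without a symbol.

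**Figure D1:**
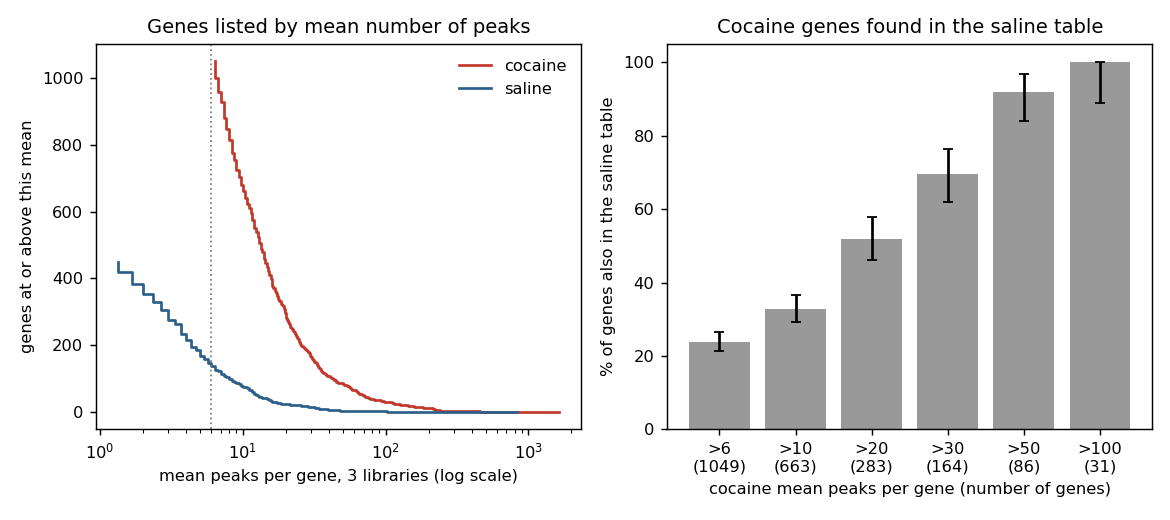
The first panel plots the number of genes (y axis) whose mean number of peaks per gene exceeds a cutoff (x axis) in the cocaine and the saline table, and the second plots the percentage of cocaine genes above a cutoff that are also in the saline table, with exact 95% binomial intervals. The percentage was 23.9% for all listed cocaine genes, 69.5% above 30 peaks and 100% above 100 peaks.

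Genes with many peaks in cocaine were listed in saline and genes with few often were not. Of the cocaine genes with more than 100 peaks, 31 of 31 were in the saline table (100%, exact 95% interval 88.8 to 100). The share was 91.9% above 50 peaks (79 of 86 genes), 69.5% above 30 (114 of 164) and 32.9% above 10. Among genes with a symbol, those with most peaks in cocaine that were missing from the saline table were Dnaja3, a mitochondrial co-chaperone gene, with 68.0 ± 20 peaks, and the non-coding Far1os, with 64.3 ± 23.1. They were followed by the non-coding 4930545L23Rik, which overlaps the phospholipase gene Plcb1 and had 50.7 ± 8.08 peaks, and by Pigc with 48.0 ± 18.5, Rnf26 with 44.7 ± 24.8, Traf3ip2 with 43.7 ± 8.96 and the non-coding Gm38505 with 41.7 ± 15.6. Epo, the erythropoietin gene, had 41.0 ± 8.54 peaks, and the non-coding 4930555F03Rik, which overlaps the teneurin gene Tenm3, had 39.0 ± 8.54. Ankk1, on chromosome 9 from 49415194 to 49427041, had 38.3 ± 11.6 and lies 7016 bases from Drd2, the gene of a dopamine receptor. The genes listed in saline and missing from the cocaine table had few peaks. Vac14 led them with 8.0 ± 2.0 peaks, followed by Npas1, a neuronal transcription factor gene, with 7.33 ± 0.577, and by Dcaf10 and Hhat with 7.0 each. Krt28 and Usp2 had 6.0 peaks each, BC107364, Fam163b and Lims2 5.67 each and Cep350 5.33. A gene missing from a table may have had peaks below that table's cutoff.

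Genes of synapses, striatal signalling and the m6A machinery were among those listed. Over all coding genes, 731 of 21896 were listed (3.34%), and the rates of the lists were not tested against this share. Of 14 gene lists fixed before the data were examined, 10 had a listed member, with 29 listed members in all. Of these, 7 were in both tables, 12 in cocaine alone and 10 in saline alone. From striatal and dopamine signalling, 2 of 49 genes were listed: Oprm1, the mu opioid receptor gene, in cocaine alone with 16.3 ± 9.45 peaks, and Gnal, the G protein subunit of striatal dopamine receptor signalling, with 8.0 ± 3.61 peaks in cocaine and 2.33 ± 0.577 in saline. From glutamate receptors and the postsynaptic density, 5 of 42 were listed. Grm5 (8.33 ± 2.08) and Lrrtm1 (14.3 ± 6.66) were in cocaine alone, Gria1 (2.67 ± 0.577) and Dlg2 (4.67 ± 1.16) in saline alone, and Dlgap1 had 8.33 ± 3.06 peaks in cocaine and 1.67 ± 0.577 in saline. From presynaptic vesicle release, 6 of 40 were listed: Syn3 and Cask in both, Erc2 and Nrxn3 in cocaine alone, and Syn2 and Gad1 in saline alone. Cask had 12.3 ± 1.16 peaks in cocaine and 3.67 ± 2.31 in saline, Erc2 14 ± 10, Nrxn3 6.33 ± 4.93, Syn2 1.33 ± 0.577 and Gad1 3.0 ± 1.73. From ion channels and pumps, 6 of 57 were listed: Cacna1d (8.67 ± 2.52), Kcnab1 (22.3 ± 13.3) and Kcnh7 (10.3 ± 4.51) in cocaine alone, and Cacna1b (2.0), Cacnb4 (1.33) and Kcnq3 (1.67) in saline alone. Among cytoskeleton and transport genes, 2 of 50 were listed, Nefm in cocaine alone with 12 ± 3.46 peaks and Kif1a in saline alone with 1.33. Among m6A writers, erasers and readers, 2 of 22 were listed: Mettl3, the m6A methyltransferase gene, in cocaine alone with 6.33 ± 5.77 peaks, and the reader gene Igf2bp3 with 32.3 ± 6.43 in cocaine and 6.0 ± 3.61 in saline. The mean of Mettl3 equals the lowest of any listed cocaine gene. Both genes overlap another, Mettl3 Tox4 and Igf2bp3 among others Malsu1.

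Of the markers of other cell types, 6 were listed. Cnp, an oligodendrocyte myelin gene that overlaps Dnajc7, had 38.7 ± 8.39 peaks in cocaine and 3.33 ± 0.577 in saline, and was the only 1 of 23 oligodendrocyte markers listed. Of 14 microglia markers, P2ry12 had 20.7 ± 3.06 peaks in cocaine and 3.0 in saline, and Cx3cr1 had 29.3 ± 5.86 in cocaine alone. P2ry12 lies within Med12l, which had 21.3 ± 9.24 peaks in cocaine and 5.0 ± 3.46 in saline, so its peaks may belong to either gene. Of 15 vascular markers, Pecam1 was in saline alone with 3.0 ± 1.0 peaks. Of 15 markers of excitatory cortical neurons, Mef2c was in cocaine alone with 18.3 ± 9.71 peaks and Cux2 in saline alone with 1.67 ± 0.577. None of the 26 immediate early genes, the 142 translation factors and ribosomal proteins, the 20 astrocyte markers or the 17 symbols of the long and mitochondrial non-coding list was in either table under its symbol. No list passed the test for over- or under-representation among genes of 1 table (2-sided Fisher's exact test over 28 tests, smallest p = 0.0944, smallest Benjamini-Hochberg adjusted p = 1.0). The smallest p within reach of a list is that with all its listed members in saline alone. In that case only the postsynaptic, presynaptic and ion channel lists could have passed after adjustment, so the tests say nothing about the other 11. With all listed members in cocaine alone, where most named genes lie, no list could have passed. Over-representation in cocaine alone was therefore not testable for any list.

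Non-coding genes made up 20.28% of the named cocaine genes (144 of 710, exact 95% interval 17.38 to 23.43) and 14.62% of the named saline genes (50 of 342, 11.05 to 18.82). Genes without a symbol could not be classed, and they were 327 of the 1049 cocaine genes and 102 of the 449 saline genes. Among genes of 1 table alone, 19.3% of 544 were non-coding in cocaine and 6.25% of 176 in saline (2-sided Fisher's exact test, p = 1.68e-05). This difference compares the 2 lists. With the cocaine list reduced to the length of the saline list it was 31.93% against 7.02% (p = 1.62e-10, Fisher's exact test). That reduction sets the cocaine genes with most peaks against all saline genes, so the peak levels are unlike. At a mean above 6 peaks in both, the order of the whole lists turned, with 20.28% non-coding in cocaine and 28.24% in saline (exact 95% interval 19.0 to 39.04). The 2 intervals overlap. This cutoff keeps all cocaine genes but only the saline genes with most peaks, so the levels are unlike here too. Only 4 named saline genes were left outside the cocaine table, none of them non-coding (Fisher's exact p = 1.0).

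The second comparison asks whether the number of peaks per gene differed between treatments among the 251 genes in both tables. More peaks were counted in cocaine for 243 of these genes and fewer for 8, with a median of 4.54 times as many (interquartile range 3.0 to 6.63). To be in both tables a gene had to pass the saline cutoff, which leaves out genes with few peaks and a high ratio. Over the 31 genes above 100 peaks in cocaine, all of them in the saline table, the median ratio was 7.49. Their summed peaks were 13861.0 ± 88.6 per cocaine library and 3273.7 ± 107.9 per saline library, a 4.23-fold difference that exceeded the spread between libraries. The exact 2-sided permutation test gave p = 0.1, the smallest that 3 libraries against 3 allow. The number of reads behind each library is unknown, and peak callers find more peaks in deeper libraries, so this difference cannot be read as a difference in binding. The 39 non-coding genes had a larger median ratio (5.8-fold) than the 127 coding genes (3.93-fold; permutation test across genes, p = 0.00096), where genes are not independent replicates.

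Each gene's share of its library's peaks in the tested shared genes was then compared, on totals scaled by TMM factors. This removes the difference in the totals of those genes, not of all listed genes. The genes in both tables held 13861.0 of 25070.0 listed peaks per cocaine library and 3273.7 of 3817.7 per saline library. Shares of all listed peaks were not tested. Of 202 genes tested with edgeR's quasi-likelihood test, 21 had a higher share and 36 a lower share in cocaine at an adjusted p under 0.05. These calls are relative to the tested genes, which were selected by both cutoffs. Of the 31 genes above 100 peaks in cocaine, 14 were called higher and 2 lower. Ctnna3 had a share higher by 1.09 on the log2 scale after TMM scaling (SE 0.17, edgeR adjusted p = 0.000199), and by 1.31 without TMM factors. Atp5o, a subunit gene of the mitochondrial ATP synthase on chromosome 16 from 91925223 to 91931630, had 201.0 ± 38.7 peaks in cocaine against 15.7 ± 0.577 in saline, a log2 difference in share of 1.37 (SE 0.25, adjusted p = 0.00077). Angptl2, which encodes a secreted angiopoietin-like protein, and Igsf8, which encodes an immunoglobulin superfamily membrane protein, had higher shares by 1.58 and 1.02. Pigk, an enzyme gene of GPI anchor attachment, and Ube3a had higher shares by 0.84 and 0.76. Rundc3b (1.35), Glp2r (0.69) and the non-coding Gm11149 (1.39) and Nrg3os (1.09) completed the 10 named genes. Glp2r (adjusted p = 0.0420) lost its call under 6 of 11 other settings and Nrg3os (adjusted p = 0.0319) under 5, and Pigk and Ube3a lost theirs without cocaine library 2 (edgeR adjusted p = 0.0615 and 0.0634). Of these 10, all but Atp5o and Igsf8 overlap another gene, such as Ncam1 for Gm11149, Nrg3 for Nrg3os and Ralgps1 for Angptl2. Over all tested coding genes, 6 of 9 with a higher share overlap another coding gene. This held for 5 of 27 with a lower share and 30 of 57 not called, and the difference was not tested. Among all 21 genes, the raw number of peaks was 7.69 to 17.9 times that of saline.

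Among the 36 genes with a lower share in cocaine, the raw number of peaks was 0.657 to 3.43 times that of saline, with a median of 1.335 against 5.0 over the other shared genes, and 10 of them had significantly more raw peaks in cocaine. Arhgap21, on chromosome 2 from 20847919 to 20968691, had 25.7 ± 4.16 peaks in cocaine and 26.0 ± 1.0 in saline, a log2 difference in share of -2.32 (SE 0.32, edgeR adjusted p = 0.000186). Sspn, a gene of the dystrophin-associated complex, had 18.3 ± 3.06 and 20.7 ± 2.31 peaks, and Zc3h7a 16.3 ± 1.53 and 18.3 ± 2.31. Kpna1, a nuclear import receptor gene, had 7.67 ± 3.06 and 11.7 ± 0.577 peaks, and Vwa3a 9.0 ± 2.65 and 13.3 ± 4.93. Filip1l, which overlaps Cmss1, had 77.3 ± 13.1 peaks in cocaine and 48.0 ± 15.7 in saline, a log2 difference in share of -1.61. Gnb1l, Dnah7b, the transcription factor gene Atf2 and Tmtc2 had between 7.0 and 13 peaks in cocaine and between 6.33 and 12 in saline, and log2 differences in share of -2.17, -2.15, -2.13 and -2.05. The leading gene without a symbol, ENSMUSG00000092329, had a lower share by a log2 difference of -1.31 (adjusted p = 1.86e-08), and ENSMUSG00000097695, also without a symbol, a higher share by 1.85.

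**Figure D2:**
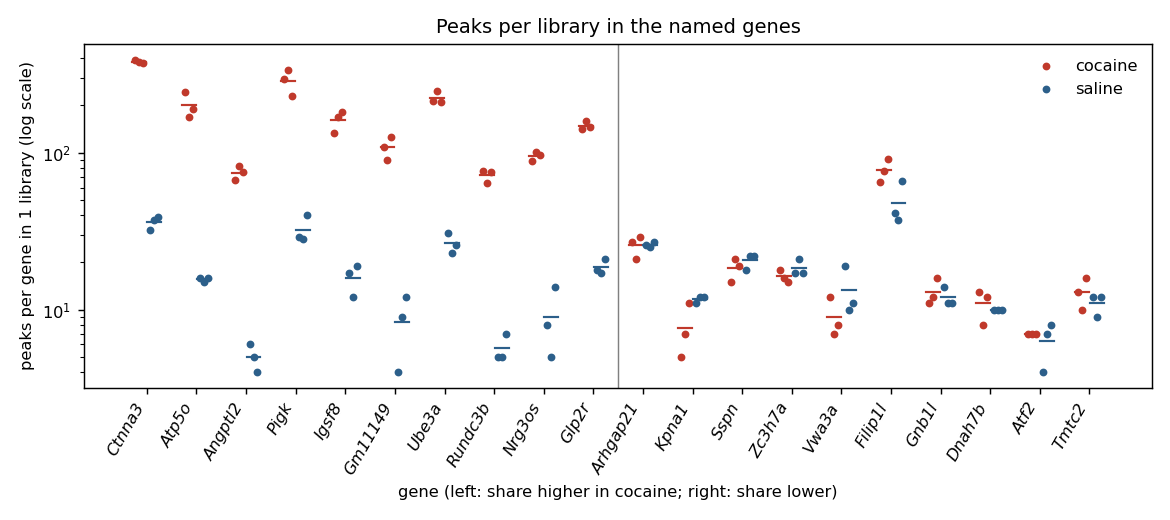
Peaks per gene in each library (points) of the 10 named genes with a higher and the 10 with a lower share of peaks in cocaine, cocaine and saline libraries in different colours, on a log axis. Genes with a higher share have many more peaks in cocaine (Ctnna3, 380.7 against 36.0), whereas those with a lower share have more similar numbers (Arhgap21, 25.7 against 26.0; Filip1l, 77.3 against 48.0).

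Of the called genes that have a class, 4 non-coding and 9 coding genes had a higher share, and 0 non-coding and 27 coding genes a lower share, against 29 non-coding and 57 coding genes not called. The higher and lower sets differed (2-sided Fisher's exact test, p = 0.00782, a test chosen after the values were seen and taken across genes, which are not independent). Peak levels were not matched in this test, and 8 of the 21 higher and 9 of the 36 lower genes had neither class. Of the fixed-list members, 4 could be tested in edgeR. None passed over all genes tested or when adjusted over the list alone, and Cnp came nearest, with a log2 difference of 1.22 (adjusted p = 0.0702 over all genes, 0.0875 over the members). A lower share is relative to the scaled total of the tested genes. On raw peaks, which move the median log2 difference by 2.28, edgeR called 176 genes higher in cocaine and 0 lower (0 at an unadjusted p under 0.05). The 176 include all 21 with a higher share. Without TMM factors 31 genes had a higher and 29 a lower share, with the median log2 difference of the tested genes moved by 0.21 (0.10 with DESeq2's size factors). The number of genes with a higher share fell from 21 to 9 without cocaine library 2 and to 13 without saline library 1.

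**Figure D3:**
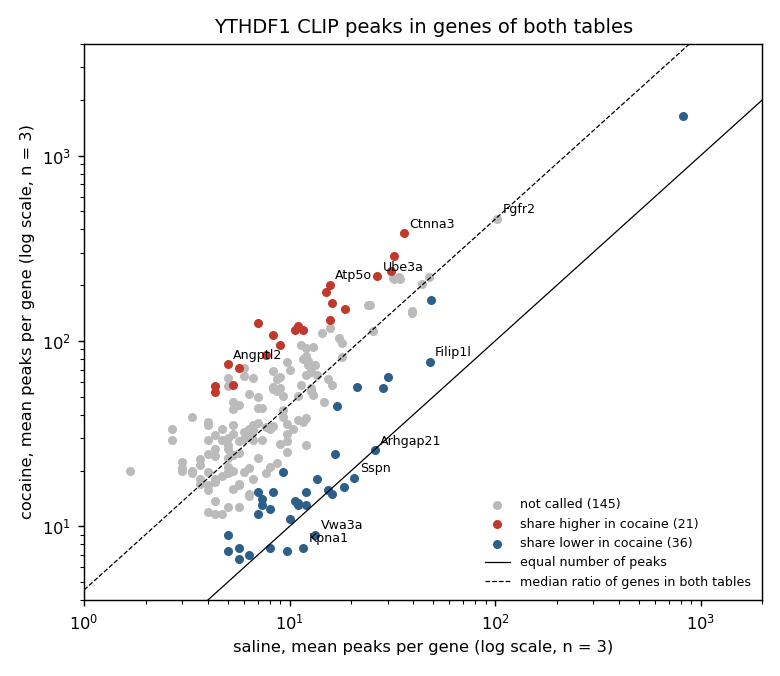
Mean number of peaks per gene in saline (x axis) and cocaine (y axis) for the 202 tested genes, both on log axes, with genes of a higher or lower share in cocaine coloured and lines for equal numbers and for the median ratio of 4.54. The 36 genes with a lower share lie below the line of the median ratio, at ratios from 0.657 to 3.43 with a median of 1.335.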

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

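Settings chosen only after the tables were seen were the common cutoff, every setting of the non-coding share, doubled cutoffs, no TMM factors, leaving out the gene with most peaks, and raw peaks. With the stricter cutoff (above the median mean of both tables), 663 cocaine and 75 saline genes were left and 73 were shared; with the common cutoff of 6 peaks, 137 saline genes were left and 132 were shared. These falls follow from keeping fewer genes. At equal list lengths, which keep the cocaine genes with most peaks, 188 were shared. With the smaller coding background, 15.1 shared coding genes were expected. The excess of non-coding genes in cocaine alone over saline alone, 13.05 percentage points, was 24.26 points with the stricter and 19.08 with the common cutoff, but no longer passed Fisher's exact test (p = 1.0 in both), where 2 and 4 named genes were left in saline alone; it was 24.91 points at equal lengths (p = 1.62e-10).

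Leaving out each library gave 9 to 20 genes with a higher share (9 without cocaine library 2, 13 without saline library 1) and 28 to 33 with a lower share; the cause was not tested. Doubled cutoffs gave 13 higher and 24 lower of 187 genes, DESeq2 22 and 29, no filter 21 and 29, no TMM factors 31 and 29 (all 21 and 29 of the original calls among them), and no leading gene 20 and 33. Raw peaks gave 176 higher and 0 lower, since the totals differ; Filip1l, Gnb1l, Dnah7b, Atf2 and Tmtc2 then turned to log2 differences of 0.69, 0.11, 0.14, 0.14 and 0.24. Over the 11 other settings, the 20 named genes gave 216 values, of which 203 kept direction and call, 13 kept direction alone (Pigk, Ube3a, Nrg3os and Glp2r) and 0 reversed. The 56 values of the gene lists under other cutoffs or lengths had a smallest adjusted p of 1.0, which says nothing about stability for lists with few listed members. No paired analysis was possible because the columns carry no replicate numbers. Merged adjacent peaks, other overlap rules, strand, peak width, locations, motifs and pseudocounts were not run, for lack of peak positions and of values that need a pseudocount.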

Other observations

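The tests of raw peaks, doubled cutoffs, other splits of the libraries, simulated tables, calls among genes above 100 peaks, opposite-strand names and overlap by gene length were chosen only after the results they bear on were seen; the tests on fixed-list genes and their neighbours were written before their results, but after overlapping genes had been noticed.

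RNAs named as transcribed from the strand opposite another gene were among those listed. Of 218 such RNAs in RefSeq, 34 were listed, 14 in both tables, 20 in cocaine alone and 0 in saline alone. The listed share of all non-coding genes is not given here for comparison, and the classes depend on the different cutoffs of the tables. Grin1os, opposite the NMDA receptor gene Grin1, had 57.7 ± 16.3 peaks in cocaine and 16 ± 8.66 in saline (SD, n = 3), while Grin1 itself was not listed under its symbol. The non-coding 1700003D09Rik, which overlaps Ppp1r1b, the gene of the striatal phosphoprotein DARPP-32, had 74.3 ± 12.9 and 13.3 ± 0.577 peaks. Gm15083, over the calcium pump gene Atp2b2, had 117.3 ± 5.51 and 15.7 ± 9.82, and Gm13872, over the astrocyte glutamate transporter gene Slc1a2, had 46.7 ± 3.51 and 14.7 ± 1.53. For 31 pairs the opposite-strand RNA alone was listed, for 17 the gene it is named after, and for 3 both (exact sign test, p = 0.0595).

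Gene lengths are given here as medians, with no test, over classes set by tables with different cutoffs. The median coding gene was 90.5 kb long when in both tables, 40.6 kb in cocaine alone and 111.1 kb in saline alone, against 17.2 kb for all RefSeq coding genes. Across genes, which are not independent, the number of peaks had a Spearman correlation of 0.0025 with length in cocaine and -0.107 in saline.

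Coding genes that overlap another gene were listed more often than those that do not: 6.97% against 1.59%, and 68.0% of the 731 listed coding genes overlap one, against 32.6% of all. The excess held within each length class, with odds ratios of 3.96 under 10 kb and 2.35 over 100 kb, so length alone does not account for it. A candidate explanation is that peaks were given to the strand opposite the transcript, but of the pairs of a fixed-list gene and an overlapping gene with 1 of them listed, the share with the partner alone was 0.424 (28 against 38 pairs, exact 95% interval 0.303 to 0.552, sign test p = 0.268), which leaves it open; counted once per fixed-list gene the share was 0.636 (28 against 16, p = 0.0961), so the lean depends on the counting. Another is that peaks in a shared stretch went to 1 of the genes: fixed-list genes without overlap should then be listed more often than other such coding genes, and the odds ratio was 1.032 (0.329 to 2.47), which decides nothing. Peak positions with strand would be needed, and no biological explanation was tested.

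The 57 genes whose share of peaks differed between treatments may reflect cocaine, the peak numbers of the libraries or the cutoffs of the tables. The cutoffs stay open as a cause. Of the 46 called genes that pass doubled cutoffs, 37 were called again (13 of 21 with a higher share and 24 of 25 with a lower share). The calls are therefore not confined to genes near the cutoffs. The log2 difference of every named gene tested there moved down, for Ctnna3 from 1.09 to 1.02 and for Arhgap21 from -2.32 to -2.39. The choice of genes thus shifted the scaling slightly. That test reused the same counts, with 187 genes against 202, so it cannot decide how far the tables' own cutoffs shifted it. A number of peaks per gene that does not grow in proportion to depth stays open: 0 of the 36 genes with a lower share had significantly fewer raw peaks in edgeR (0 at an unadjusted p under 0.05), but only 15 had over 12 peaks in saline, and a gene losing more would leave the cocaine table. The 10 splits of the 6 libraries are too few for a share under 0.05; the real split gave 57 genes, the highest other 0, and 1 of 10 gave as many. An effect of cocaine on binding stays open as well, since peak totals and treatment go together in these libraries and their depth is unknown.

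Most cocaine genes were missing from the saline table. A ratio of peaks shared by every gene is argued against for the genes with most peaks, by the spread of their ratios. Of the 31 genes above 100 peaks in cocaine, all of them in the saline table, edgeR called 16 to differ in share (14 higher, 2 lower), with raw ratios from 1.99 to 17.9. The 14 higher calls cannot count against 1 ratio, because edgeR centres on the tested genes. The median ratio was 4.54 over the shared genes and 7.49 over these 31. Only the spread of ratios bears on whether 1 ratio held for these 31 genes. The median ratio of the 31 genes gave 508 to 597 shared genes in 1000 simulated tables with the same cutoffs and the common dispersion, against 251 observed. Their highest ratio gave 193 to 258. The simulation took as true the cocaine means of genes chosen for passing the cutoff, and used the dispersion of the tested shared genes. Genes in cocaine alone may vary more, and both choices can raise the simulated sharing. Whether the cutoffs at 1 ratio would leave so few shared genes therefore stays open. Cutoffs together with ratios that differ between genes stay open, as this was not tested. Whether weakly bound RNAs dropped below detection in the saline libraries or carried less YTHDF1 was not tested either, since neither depth nor input values were used here.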
